A study of Gallus gallus and Dromaius novaehollandiae and Alligator mississippiensis with 60 samples.

How the data were processed

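The samples were epidermis of chicken, emu and alligator embryos and dermis of chicken embryos, and per the labels' protocols the layers were parted with dispase at 10 mg/mL and 4 °C for 13 h. Chicken eggs were kept at 37.8 °C and emu eggs at 35.5 °C. Per the labels' protocols total RNA was extracted with a column kit, and strand-specific libraries were made from polyadenylated RNA. The submitters' processing notes name CASAVA, TopHat2 2.0.6 and HTSeq 0.5.3p9, with no role or order. The genome builds and annotations are not given in the sources used here. The deposited values are in TPM, a transcript abundance scaled to gene length and library total, in a single table of 17889 genes by 60 libraries that carries chicken gene identifiers for every species. TPM sets a gene's reads against its length and against the sum over all genes of the library, so a change in a few abundant genes shifts all others. The top 10 genes took 7.1% to 15.8% of a library's total. Emu and alligator columns had near-constant totals, from 549879 to 549939 over 8749 genes and from 619786 to 619877 over 9295 genes. Chicken means over the same genes were 551983 and 614582, and the sources used here do not state how the emu and alligator columns were scaled. Levels are therefore compared within species, and effects between species. Chicken totals ran from 994044 to 999897. A value was present in all 3 species for 6150 genes. TPM keeps no read depth, so no counting interval or detection floor was computed, and a value of 0 means only that the gene was listed at 0.

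Groups were taken from the labels, by species, appendage, stage and layer. The series' design text calls the replicates biological, and the titles give libraries of a group separate specimen numbers. Dorsal and femoral feather libraries of a stage share specimens, so that 4 libraries came from 2 specimens in chicken and 3 in emu, and they entered the fits as separate libraries. The labels do not say more of how embryos were drawn, so p-values measure only the spread between these libraries. Among 1770 pairs of libraries 0 held identical values, and all per-sample columns were used. The groups, comparisons, tests, named-gene rule and most alternatives were fixed before the data were examined. Comparisons were fitted with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean for each group, eBayes with trend and robust shrinkage, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. A gene entered a fit where it reached 1 TPM in at least 2 libraries of each species in it: 6776 genes for birds, 4671 for all 3 species, 7811 for alligator, 13645 for chicken layers and 12860 for chicken dermis. Contrasts over species weighted each species equally, and contrasts over feathers weighted both tracts equally. Chicken dermis against epidermis was fitted with additive terms for the 10 classes of appendage and stage, and feather against scutate dermis with appendage and stage terms. Chicken minus emu differences were taken as contrasts in the same fit. The scutate, reticulate and claw samples were older than feather samples of the same stage name, so age and appendage are joined in several comparisons, and comparisons nearer in age were among the alternatives. Gene sets were tested with camera at its preset correlation and again with an estimated correlation, and with fry, whose p is given for the bird sets read in alligator. Sets read in alligator were defined in birds alone, except for alternative sets defined against bird claw. Those were contrasts of birds called in the fit of all 3 species, which holds the alligator libraries. Correlations of log2 differences are across genes, with a jackknife SE over libraries.

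The named-gene rule called for the 6 genes with the largest change each way among called genes with a symbol and the same sign in every part of the comparison (4 each way in the lesser comparisons), plus members of fixed gene lists. Of the table's identifiers, 0 matched the symbols of the reference used here, so symbols could not be given, and the 21 gene lists fixed beforehand (signalling pathways, patterning genes, markers of other cell types) could not be applied. At most 2 identifiers higher and 2 lower are named in each of 7 comparisons, those with the largest called change of the same sign in every species, or at both stages within alligator, or in at least 9 of 10 classes for dermis. Groups defined from the data took the place of the lists, namely genes 4-fold or more higher in chicken dermis or epidermis, genes higher in an appendage than in each other, and genes called in birds and read in alligator. The layer lists and the groups restricted to an appendage were chosen after seeing that symbols were missing, while the bird sets read in alligator had been fixed before.

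The specimen numbers in the titles were checked for pairing. Over 8 pairs of bird epidermis libraries of the same number and stage label, the deviations from group means correlated at 0.13 to 0.36, each over 0.1, so the numbers were taken to pair the libraries. In groups of 2 the deviations mirror each other, so the chicken tract pairs of a stage repeat the same value (0.36). The 8 pairs are thus not separate checks, and libraries of different specimens were not set beside them. The block was fitted with duplicateCorrelation, and its estimated correlation was 0.332 in the bird fit. It was 0.312 in the fit of all 3 species, -0.091 in that of the chicken layers and 0.881 in that of chicken dermis. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-of-ratios rescaling within species, quantile normalization, eBayes without trend or robust shrinkage, array weights, the replicate block, species fitted alone, comparisons nearer in age, and each library left out in turn. A term for the kinds of chicken library and the removal of genes 2-fold or more higher in dermis were chosen after seeing the data. So were all alternatives for alligator scale against claw, the claw effect in alligator minus birds and in chicken minus emu, the change with stage of feather minus scutate scale and of alligator femoral minus flank scale, and the genes restricted to an appendage. The limma calling was tested for 5 comparisons on simulated data made from each gene's real mean and residual spread, with 200 changed genes. Noise was drawn independently for each library, so simulated libraries of a specimen were not correlated. The real fits of these comparisons called 264 to 8702 genes. The simulated shares below therefore need not hold for the real calls. Set tests, correlations and the other comparisons were not simulated. For feather against scutate placode over 6776 genes, 91% of 100 genes changed 2-fold and 98% of 100 changed 4-fold were recovered, and 5.5% of calls were false. The false share was 4.3% for claw, 4.9% for alligator femoral against flank scale, 3.6% for chicken layers and 6.5% for the chicken minus emu difference. Recovery was 100% and 100% for claw over 4671 genes, 97% and 99% for alligator femoral against flank scale over 7811, 91% and 97% for chicken layers over 13645, and 70% and 88% for the chicken minus emu difference over 6776. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.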

Results

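The series measured RNA in the developing skin appendages of chicken, emu and alligator embryos, and its title concerns an ancestral scale programme divided between feathers and the scutate scales of birds. Scutate scales are the broad overlapping scales on the front of a bird's foot, and reticulate scales are the small rounded scales of the foot pad. There were 60 libraries in 36 groups: 30 from chicken, 18 from emu and 12 from alligator. Chicken and emu appendages were dorsal feather, femoral feather, scutate scale, reticulate scale and claw, and alligator appendages were flank scale, femoral scale and foot claw. Each was taken when the placode, the first epidermal thickening, had formed and again during morphogenesis, when the appendage takes shape. In birds the placodes came from Hamburger and Hamilton stages 33 to 34 (feather), 36 (claw), 37 (scutate) and 39 (reticulate), and the later samples from stages 36 (feather), 38 (claw) and 40 (both bird scales). The alligator placodes came from Ferguson stage 22 for flank scale and 21 for femoral scale and claw, and the later samples from stages 23, 23 to 24 and 22. Chicken also gave 10 dermis libraries, 1 per appendage and stage, and epidermis groups held 2 libraries each, except emu reticulate placode and emu claw placode with 1. Emu columns held values for 8749 genes and alligator columns for 9295, against 17889 in chicken. The number of genes at 1 TPM (a length- and total-scaled transcript abundance) or more ran from 10860 to 12158 in chicken, from 6451 to 6941 in emu and from 7127 to 7569 in alligator. Read depth behind the values is unknown. Lane numbers in the titles carry no run name, so equal lane numbers need not be the same run. Genes appear below by the chicken identifiers that the deposited table carries, and the error of a log2 difference is its standard error (SE).

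On the first principal component the claw groups had the highest means in each of the 3 species. With each species centred on its own mean, this component of the epidermis libraries carried 34% of the variance over 4671 genes, and the second 12%. The claw libraries at morphogenesis averaged 50.6 in chicken, 41.6 in emu and 33.2 in alligator, and at placode 31.2, 25.5 and 6.3. Alligator claw placode replicate 2 (1.58) lay below alligator femoral scale morphogenesis replicate 1 (2.95). On the second component alligator claws averaged 24.6 at placode and 36 at morphogenesis, and alligator scale groups -17.7 to -13.3. Feather groups lay at the opposite end, from -30.6 for chicken femoral feather placode to -13.5 for emu femoral feather morphogenesis. Alligator flank and femoral scales at placode averaged -15 and -18.2. Several scale groups lay nearer the claw side at morphogenesis than at placode. In chicken the means were -15.5 and 15.8 for scutate and -2.8 and 20.9 for reticulate scale, in emu -5.2 and -4 for scutate and -1.5 and 13.9 for reticulate scale, and at morphogenesis alligator flank and femoral scales averaged -8.1 and 1.7. The 24 replicate pairs correlated at 0.919 to 0.995 across genes (median 0.9825). The lowest pair was chicken claw placode, whose replicate 2 lay above replicate 1 in 991 of 1101 dermis-enriched genes, and all others reached 0.964 or more.

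**Figure D1:**
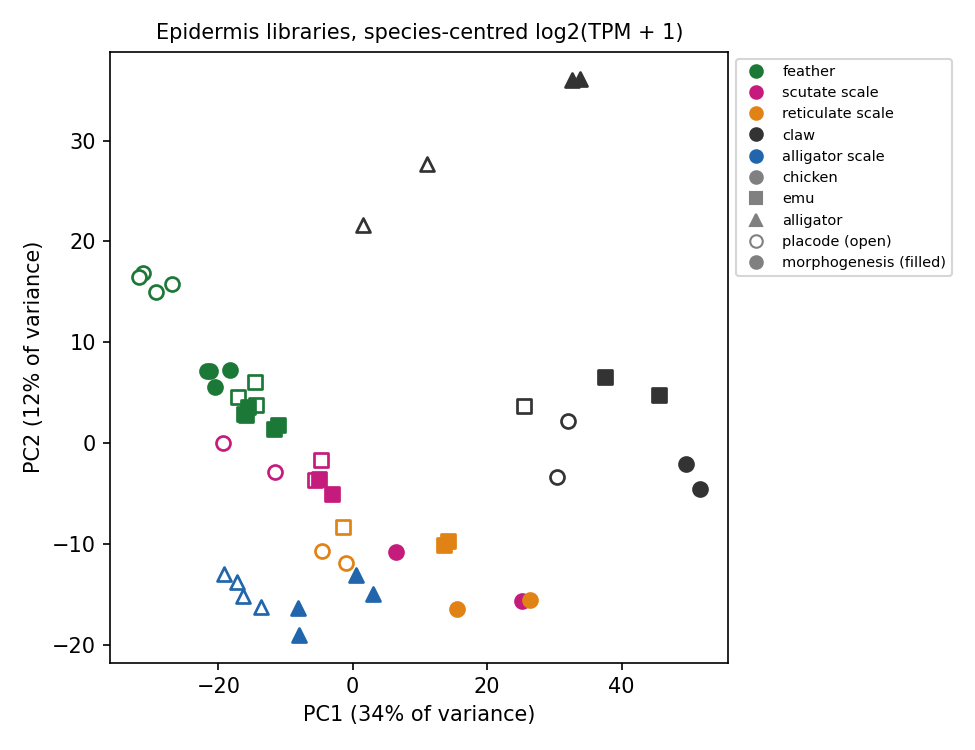
Scores of the epidermis libraries on the first 2 principal components of species-centred log2(TPM + 1), which carry 34% and 12% of the variance, with a point per library marked by appendage, species and stage. Claw libraries lie to the right of the other appendages of their species and stage, and feather libraries to the left.

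The appendages of chicken and emu matched each other by type. Of the 10 chicken epidermis groups, 9 correlated best, over 6776 genes, with an emu group of the same appendage. The best correlations were 0.38 for dorsal feather placode, 0.4 for femoral feather placode, 0.32 for scutate placode, 0.26 for reticulate placode and 0.5 for claw morphogenesis. The exception was chicken scutate scale at morphogenesis, which lay closest to emu reticulate scale at morphogenesis (0.29) and reached 0.01 with emu scutate scale at the same stage. Replicates 1 and 2 of that chicken group lay apart on the first principal component (25.13 and 6.46). The correlations were not taken for single libraries, so whether 1 of them brings about the exception was not tested. These are correlations across genes, which are not independent replicates.

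**Figure D2:**
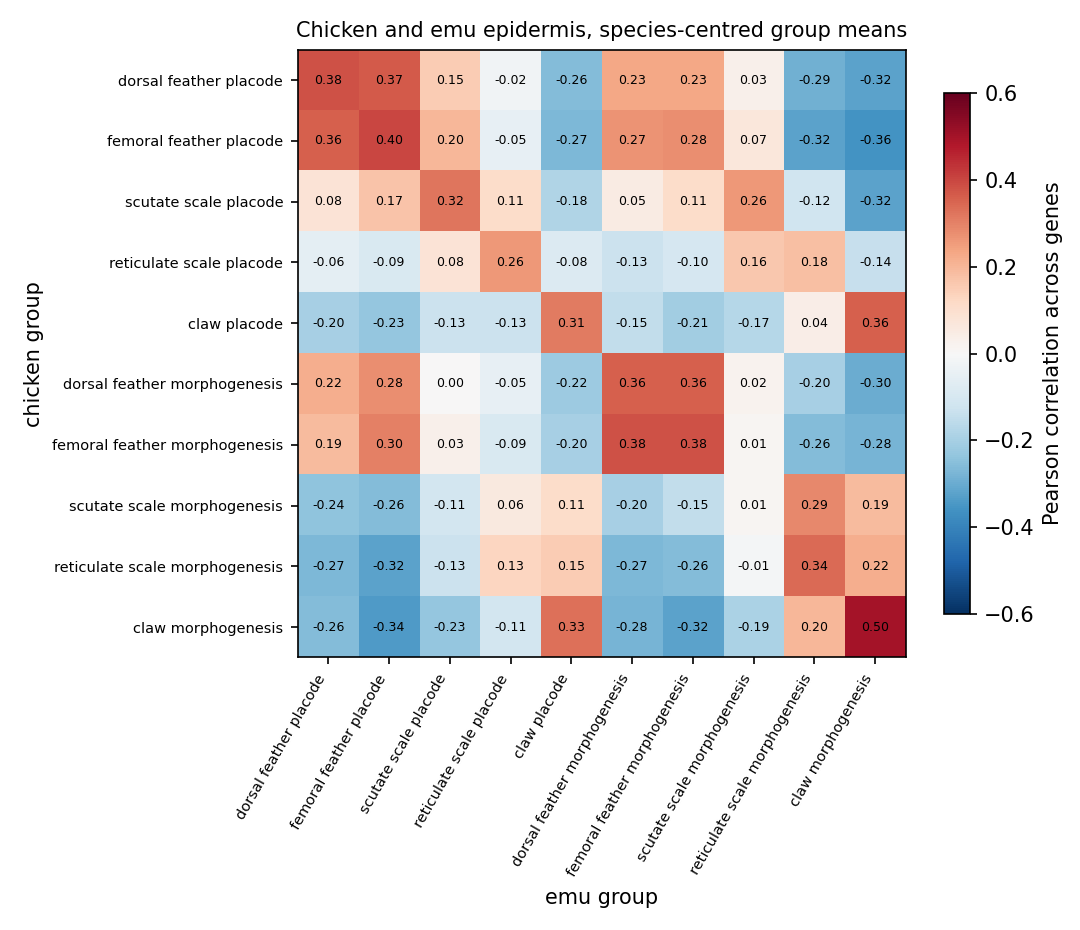
Pearson correlation across 6776 genes between chicken group means (vertical axis) and emu group means (horizontal axis), each centred on its species, with red positive and blue negative. The highest value of a chicken group falls on the same appendage in emu for 9 of 10 groups, and chicken scutate morphogenesis is the exception (0.29 with emu reticulate morphogenesis).

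Feather placodes and scutate scale placodes differed in 1530 of 6776 genes across chicken and emu, of which 998 were higher in feather and 532 higher in scutate scale. The difference was at least 2-fold for 200 and 104 of these, and 89% of the called genes had the same sign in both birds. ENSGALG00000015205 was higher in feather by 6.46 on the log2 scale (SE 0.77, adjusted p = 3.3e-06). It averaged 102 ± 85.2 TPM in chicken feather placodes and 224 ± 240 in emu (SD, n = 4 libraries each), against 0.0571 ± 0.0807 and 0.31 ± 0.322 in scutate placodes (n = 2 each). The 4 feather libraries were both tracts of 2 chicken specimens, and in emu of 3 specimens, and tracts of a specimen are counted here and below as separate libraries. ENSGALG00000007466 was higher in feather by 5.58 (SE 0.61, adjusted p = 1.2e-06), at 296 ± 61.2 against 0.307 ± 0.395 TPM in chicken and 188 ± 80.6 against 17.1 ± 5.9 in emu, a difference larger in chicken than in emu by 4.52 (SE 1.23, adjusted p = 0.019). On the scutate side, ENSGALG00000010923 differed by -4.11 (SE 0.17, adjusted p = 5.1e-14), with 26.9 ± 5.71 TPM in chicken and 53.8 ± 20.3 in emu scutate placodes against 2.26 ± 0.238 and 0.551 ± 0.435 in feather, and its difference was less negative in chicken than in emu by 2.05 (SE 0.34, adjusted p = 0.00034). ENSGALG00000008250 differed by -4.04 (SE 0.16, adjusted p = 2.2e-14), with 77.2 ± 29.1 and 67.8 ± 11.5 TPM in scutate placodes against 5.29 ± 4.38 and 3.03 ± 1.58 in feather. Genes enriched in chicken epidermis over dermis were more often higher in scutate placodes, with 74 of 237 higher there and 24 higher in feather (camera adjusted p = 9.5e-09, and adjusted p = 0.1 with an estimated correlation). Dermis-enriched genes went the other way, with 132 of 447 higher in feather and 23 in scutate scale (camera adjusted p = 0.00012, and adjusted p = 0.92 with an estimated correlation). The split by direction depended on the scaling: after median-of-ratios rescaling it was 812 to 779 and after quantile normalization 752 to 757, so which side held more genes was not fixed. Feather placodes also came from younger embryos. Feather at morphogenesis (stage 36) against scutate scale at placode (stage 37) gave 2094 genes, with 789 of the 1530 among them. Both contrasts used the same scutate placode libraries, which by itself makes the lists overlap, so the 789 do not show how many differences are free of age. In emu, feather placodes came from lanes 6 and 7 (1 library has no lane number) and scutate placodes from lane 2, so lane and appendage cannot be told apart in emu.

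At morphogenesis feather and scutate scale differed in 2871 genes, 2098 higher in feather and 773 higher in scutate scale. The difference reached 2-fold for 231 and 146 of them, and 87.5% had the same sign in both birds. Of the genes higher in feather at placode, 612 were again higher at morphogenesis, against 309 for independent lists, and 268 of those higher in scutate scale were again so, against 60.7. The log2 differences of the stages correlated at r = 0.62 and rho = 0.46 across genes, from separate libraries. Feather came from younger embryos than scutate scale at placode and again here (stage 36 against 40). An effect of age would recur in the same way, so the overlap cannot tell age and appendage apart. No comparison nearer in age was run at morphogenesis. ENSGALG00000010923 (log2 difference -4.81, SE 0.17, adjusted p = 5.3e-15) and ENSGALG00000008250 (-3.97, SE 0.16, adjusted p = 2.2e-14) led the scutate side again. In scutate scale ENSGALG00000010923 stood at 65.7 ± 21.95 TPM in chicken and 78.4 ± 7.29 in emu (n = 2 each). ENSGALG00000016899 was higher in feather by 4.7 (SE 0.71, adjusted p = 2.9e-05), at 69.9 ± 28.7 and 76 ± 30.6 TPM in chicken and emu feather (n = 4 each). ENSGALG00000015205 was higher in feather by 4.64 (SE 0.77, adjusted p = 7.6e-05), although in chicken alone its adjusted p was 0.15, since the chicken scutate libraries stood at 0.0709 and 52.1 TPM. Of 237 epidermis-enriched genes, 123 were higher in scutate scale and 25 in feather (camera adjusted p = 4.5e-22, and adjusted p = 0.011 with an estimated correlation), while 36.7% of 447 dermis-enriched genes were called higher in feather and 31 genes in scutate scale, with a median 0.297 above that of the other genes (adjusted p = 0.048, and adjusted p = 0.95 with an estimated correlation). The median of all genes lay at 0.131 as deposited and at 0.013 after median-of-ratios rescaling. Relative to that median the directions were near even, with 1267 to 1213 genes after rescaling and 1339 to 1145 after quantile normalization.

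Part of the feather to scutate contrast was shared by the birds. At placode, 133 genes were called higher in feather in chicken and in emu fitted side by side, against 63.2 for independent lists, and 76 were called higher in scutate scale in both, against 22.4. In 28 and 21 genes the calls were opposite. The log2 differences of chicken and emu correlated across 6776 genes at r = 0.268 (jackknife SE 0.033 over libraries) and rho = 0.178. The test of the difference between the birds itself called 865 genes, 432 with a larger feather minus scutate value in chicken and 433 in emu. At morphogenesis the shared lists held 399 genes higher in feather and 142 higher in scutate scale, against 241.1 and 52.9, and the calls were opposite in 88 and 42. The count of 865 fell to 485 without chicken scutate scale placode replicate 2 and to 452 without emu scutate scale placode replicate 1.

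Reticulate and scutate scales, compared at stage 40 in both birds, differed in 1209 genes, of which 440 were higher in reticulate and 769 in scutate scale. The difference was at least 2-fold for 25.9% of the first and 12.2% of the second. ENSGALG00000020671 was higher in reticulate scale by 3.81 (SE 0.37, adjusted p = 7.4e-07), at 685 ± 136 against 28.3 ± 5.02 TPM in emu (n = 2 each). In chicken it stood at 3.28 and 15.8 TPM in the reticulate libraries and was listed at 0 in both scutate libraries. ENSGALG00000017119 was higher in scutate scale, with a log2 difference of -3.29 (SE 0.22, adjusted p = 4e-09) and 167 ± 43.2 against 13.2 ± 3.4 TPM in chicken and 577 ± 37.5 against 70.3 ± 2.86 in emu. ENSGALG00000015764 (2.8, SE 0.61, adjusted p = 0.0032) and ENSGALG00000016584 (-2.91, SE 0.73, adjusted p = 0.0087) passed the threshold over both birds but not in chicken alone (adjusted p = 0.074 and 0.91). In chicken alone the log2 difference was 3.72 for the first and -0.64 for the second. Without chicken scutate scale morphogenesis replicate 2, ENSGALG00000016584 had an adjusted p of 0.069. Of the epidermis-enriched genes, 52 of 237 were higher in reticulate scale and 15 in scutate scale (camera adjusted p = 6.3e-09, and adjusted p = 0.1 with an estimated correlation). The split by direction was 637 to 502 after median-of-ratios rescaling and 592 to 631 after quantile normalization, so the side with more genes depended on the scaling. Leaving out 1 library gave 715 genes without chicken scutate scale morphogenesis replicate 2, 721 without emu scutate scale morphogenesis replicate 2 and 714 without emu reticulate scale morphogenesis replicate 2, chicken alone gave 375, and the emu libraries of the 2 scales ran in different lanes (1 and 2), so lane and scale cannot be told apart in emu.

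Claws, compared with feathers and scutate scales in birds and with body scales in alligator, differed in 3630 of 4671 genes, 1093 higher and 2537 lower in claw, by at least 2-fold in 15% and 10.5% of these. ENSGALG00000010923 was higher in claw by 6.13 (SE 0.1, adjusted p = 1.5e-27), and its claw level was 540.1 ± 62.6 TPM in chicken (n = 4), 995 ± 105 in emu (n = 3) and 302 ± 15.5 in alligator (n = 4). In the reference appendages it stood at 16.8 ± 25.7, 22.7 ± 33.5 and 3 ± 1.41 TPM. ENSGALG00000001281 was higher in claw by 4.19 (SE 0.17, adjusted p = 7.5e-19), at 144 ± 106, 25.6 ± 17.3 and 93.6 ± 71.4 TPM in the same order, and its claw effect was larger in alligator than in birds by 2.07 (SE 0.35, adjusted p = 5.6e-06). ENSGALG00000014908 was nearly absent from claw, with a log2 difference of -4.97 (SE 0.16, adjusted p = 2.8e-20). Its claw levels were 0.497 ± 0.555, 0.872 ± 0.18 and 0.418 ± 0.477 TPM, against 49.8 ± 50.2, 54.5 ± 28.6 and 132 ± 30.1 elsewhere (n = 12, 12 and 8), and its claw effect was more negative in alligator than in birds by a log2 difference of -2.39 (SE 0.34, adjusted p = 4.3e-07). ENSGALG00000016584 was lower in claw by a log2 difference of -4.66 (SE 0.36, adjusted p = 6.5e-12), less so in alligator than in birds by 2.5 (SE 0.76, adjusted p = 0.0046). Of 149 epidermis-enriched genes, 77 were higher and 53 lower in claw and 19 were not called (camera adjusted p = 6.5e-06, and adjusted p = 0.14 with an estimated correlation). Called in each species separately over these genes, 617 were higher and 2919 lower in claw in chicken, and 875 and 2192 in emu. In alligator 1958 were higher and 1391 lower, so the pooled excess of lower genes was not seen there. In all 3 species 209 genes were higher in claw and 702 lower, against 48.4 and 407.9 for independent lists. Of the 3630 genes, 50.6% had the same sign in every species. The median of all genes was -0.183 as deposited and -0.002 after median-of-ratios rescaling, and the split was then 1749 to 1728 (1587 to 1802 after quantile normalization), so the excess of lower genes was gone after the first and smaller after the second. In alligator each appendage ran in its own lanes (claw 1 and 2, femoral scale 3, flank scale 7), so lane and appendage cannot be told apart there.

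Feather and scutate scale of birds were each set against claw and compared with alligator scale against claw. In both contrasts 1040 genes were higher in feather and in alligator scale than in claw, against 904.7 for independent lists, while 1063 were higher in feather and lower in alligator scale. For genes lower than in claw these numbers were 439, 310.2 and 138. For scutate scale, 966 genes were higher in both, against 787.4, with 842 opposite, and 493 were lower in both, against 332.4, with 134 opposite. Feather was higher than claw in 3038 genes and lower in 740, scutate scale in 2644 and 793, and alligator scale in 1391 and 1958. No number for independent lists was computed for the opposite calls, so they cannot be read against the shared ones. These lists were called on the values as deposited and were not called anew after rescaling. Across 4671 genes, feather minus claw in birds correlated with scale minus claw in alligator at r = 0.391 and rho = 0.327 (jackknife SE of r 0.017). Scutate scale minus claw in birds correlated with the same alligator contrast at r = 0.376 and rho = 0.341 (jackknife SE 0.023). No library enters both sides of either correlation. The difference between the correlations was not tested. Genes are not independent replicates.

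Genes that set feather and scutate scale apart in birds were next read in alligator, where scale and claw differed in 5694 of 7811 genes (2413 higher in scale, 3281 in claw). The median of all genes there moved from -0.089 as deposited to 0.025 with quantile normalization, and the split was 2855 to 2919 after median-of-ratios rescaling and 2916 to 2716 after quantile normalization, so the side with more genes depended on the scaling. Of 697 genes higher in feather placodes than in scutate placodes, 186 were higher and 346 lower in alligator scale than in claw. With the set called anew after each rescaling these were 188 and 240 of 561 (median-of-ratios) and 181 and 203 of 527 (quantile). Their median was 0.113 below that of the other genes, which the competitive test did not separate from them (camera adjusted p = 0.42, and adjusted p = 0.83 with an estimated correlation). The other genes here and below are the rest of the 7811, of which only 4671 were also tested in both birds. Genes not tested in birds could not enter a set, so a set and the other genes could differ in make-up for that reason alone. Of 353 genes higher in scutate placodes, 156 were higher in alligator scale, 32.9% were lower and 81 genes were not called, with a median 0.24 above the other genes (camera adjusted p = 0.033, and adjusted p = 0.83 with an estimated correlation). With quantile normalization that difference was 0.079 (camera in limma, unadjusted p = 0.51). Tested alone and not against other genes, the feather-higher set lay on balance lower in alligator scale (fry in limma, unadjusted p = 0.00054) and the scutate-higher set did not pass (unadjusted p = 0.12). The fry test was run only on the values as deposited, where the median of all genes was itself -0.089, so its direction cannot be told apart from the scaling. The feather set reversed sign to 0.149 when defined against bird claw in place of scutate scale, a set of 3038 genes (camera in limma, unadjusted p = 0.029, against 0.21 for the set of 697).

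Many genes were higher in feather than in each other bird appendage. Of 6776 genes, 1590 were higher in feather than in scutate scale, reticulate scale and claw alike, 616 were higher in claw than in every other appendage, 387 in reticulate scale and 97 in scutate scale. Of these 104, 153, 37 and 6 exceeded each other appendage by at least 2-fold. Of 409 claw-restricted genes tested in alligator, 274 were higher in claw, 58 were higher in scale and 77 were not called (camera adjusted p = 1.2e-06, and adjusted p = 0.72 with an estimated correlation). The genes they were set against again included genes not tested in birds. The feather and claw counts depended on the scaling, with 737 and 1423 genes after median-of-ratios rescaling and 836 and 1173 after quantile normalization, which reverses their order.

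Femoral and flank scales of the alligator, which the sample labels call asymmetric and symmetric, differed in 264 of 7811 genes, of which 57.2% were higher in femoral scale and the rest higher in flank scale. The series' design text speaks of dorsal scales where the sample labels give the flank. ENSGALG00000016740 was higher in femoral scale by 1.75 (SE 0.14, adjusted p = 2e-04), at 21 ± 23.7 against 2.29 ± 1.82 TPM (n = 4 each). ENSGALG00000003323 was higher there by 1.79 (SE 0.33, adjusted p = 0.02), at 11.9 ± 14.9 against 0.859 ± 0.701 TPM. The femoral excess of both genes was larger at morphogenesis than at placode, by 2.66 (SE 0.28, adjusted p = 0.00094) for ENSGALG00000016740 and 3.11 (SE 0.66, adjusted p = 0.02) for ENSGALG00000003323. The second gene passed the threshold no longer in 4 of the 8 fits that left out 1 library, where its adjusted p was 0.063 to 0.1: without flank scale placode replicate 1 or 2, flank scale morphogenesis replicate 2 or femoral scale morphogenesis replicate 1. On the flank side, ENSGALG00000007219 (-2.13, SE 0.12, adjusted p = 1.7e-05, more negative at morphogenesis by -2.5, SE 0.25) stood at 26.6 ± 1.33 against 8.1 ± 7.58 TPM, and ENSGALG00000019869 (-1.9, SE 0.17, adjusted p = 0.00041) at 3.3 ± 1.54 against 0.0978 ± 0.104. Leaving out a library gave 80 and 63 genes without flank scale placode replicates 1 and 2, 94 higher and 58 lower without flank scale morphogenesis replicate 1, 91 in all without its replicate 2, and 89 and 129 without femoral scale morphogenesis replicates 1 and 2, while array weights gave 769. Quantile normalization gave 455 genes with a split of 197 to 258, the femoral libraries ran in lane 3 and the flank libraries in lane 7, and lane and scale cannot be told apart.

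Dorsal and femoral feather tracts were nearly alike in these libraries, with 3 of 6776 genes called and 558 at an unadjusted p under 0.05. ENSGALG00000002393 was higher in dorsal feather by 1.02 (SE 0.12, adjusted p = 0.00011), at 56 ± 10.6 against 39.9 ± 5.62 TPM in chicken and 118 ± 13.8 against 45.7 ± 28.2 in emu (n = 4 each), and in chicken alone its log2 difference was 0.47 (adjusted p = 1). ENSGALG00000008250, which also marked scutate scale, was higher in femoral feather, with a log2 difference of -1.38 (SE 0.13, adjusted p = 2.6e-06) and 10.5 ± 4.01 against 1.31 ± 0.267 TPM in chicken. In emu it stood at 2.64 ± 2.06 against 1.27 ± 0.509 TPM and did not pass the threshold alone (adjusted p = 0.2). ENSGALG00000011369 was also higher in femoral feather (-0.82, SE 0.15, adjusted p = 0.031), but it was lost in 12 of the 16 fits that left out 1 library (adjusted p 0.056 to 0.15). With the specimen number as a replicate block, 75 genes were called (59 higher in dorsal, 16 in femoral). With specimen as a fixed term, and only feather libraries of specimens sampled in both tracts, limma called 0, with 704 at an unadjusted p under 0.05. The count was 5 without chicken femoral feather placode replicate 2, 12 without emu dorsal feather placode replicate 1 and 6 without emu femoral feather placode replicate 2.

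Between placode and morphogenesis, feather changed in 2239 of 6776 bird genes, with 1322 higher later and 917 higher at placode. Scutate scale changed in 875, with 378 higher later and 497 higher at placode. Claw, over all 3 species, changed in 2398 of 4671 genes, 538 higher and 1860 lower at morphogenesis, and alligator scale in 3372 of 7811, 905 higher and 2467 lower. Of 237 epidermis-enriched genes, 74 were higher and 23 lower at morphogenesis in scutate scale and 140 were not called (camera adjusted p = 2.1e-09, and adjusted p = 0.1 with an estimated correlation). In claw 56 were higher, 33 lower and 60 not called of 149 (adjusted p = 1.8e-08, and adjusted p = 0.1 with an estimated correlation), and in alligator scale 94, 45 and 105 of 244 (adjusted p = 2.1e-09, and adjusted p = 0.21 with an estimated correlation). In feather 62 were higher and 59 lower at morphogenesis (adjusted p = 0.81). In chicken and emu fitted side by side, 201 genes rose with stage in feather in both birds, against 101.6 for independent lists, and 153 fell in both, against 60, while 40 and 54 changed in opposite directions. The median of all genes moved from -0.185 to 0.009 for claw and from -0.133 to 0 for alligator scale on median-of-ratios rescaling, and relative to it the splits were 1144 to 951 and 1478 to 1368 (875 to 1066 and 1420 to 1738 after quantile normalization), while those of feather and scutate scale were 1124 to 1114 and 461 to 423 (1268 to 1132 and 458 to 493), so in all 4 the side with more genes was not fixed or its excess shrank. For scutate scale, chicken alone gave 2407 genes and emu alone 2, and the pooled count was 423 without chicken scutate scale placode replicate 1, 357 without chicken scutate scale morphogenesis replicate 1, 537 without emu scutate scale placode replicate 1 and 491 without emu scutate scale morphogenesis replicate 1.

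Dermis and epidermis of the chicken differed in 8702 of 13645 genes, with 5010 higher in dermis (2410 by at least 2-fold) and 3692 higher in epidermis (1041 by at least 2-fold). ENSGALG00000004732 was higher in dermis by 8.24 (SE 0.42, adjusted p = 1.2e-13), at 571 ± 278 TPM in dermis (n = 10) against 2.84 ± 8.56 in epidermis (n = 20). ENSGALG00000004274 was higher by 8.09 (SE 0.47, adjusted p = 9.2e-13), at 822 ± 363 against 3.95 ± 8.61 TPM. ENSGALG00000007280 (-6.88, SE 0.38, adjusted p = 3.5e-13) and ENSGALG00000008424 (-6.85, SE 0.32, adjusted p = 2.7e-14) marked the epidermis, at 951 ± 475 and 908 ± 245 TPM against 14 ± 24.8 and 10.7 ± 10.1. Both dermis genes were highest among epidermis libraries at 36.8 and 38.4 TPM. With a cutoff of 4-fold, 1101 genes formed the dermis-enriched list and 438 the epidermis-enriched list used above. These lists were chosen on the chicken libraries, so their counts in comparisons with chicken libraries are not independent evidence of direction. In chicken epidermis the mean log2(TPM + 1) of the 456 dermis-enriched genes measured in all 3 species was 1.9 ± 0.09 in feather (SD, n = 8), 1.39 ± 0.13 in scutate scale, 1.39 ± 0.09 in reticulate scale and 1.79 ± 0.57 in claw (n = 4 each). In emu it was 2.5 ± 0.2 in feather (n = 8), 2.29 ± 0.03 in scutate scale (n = 4) and 2.17 ± 0.29 in claw (n = 3).

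**Figure D3:**
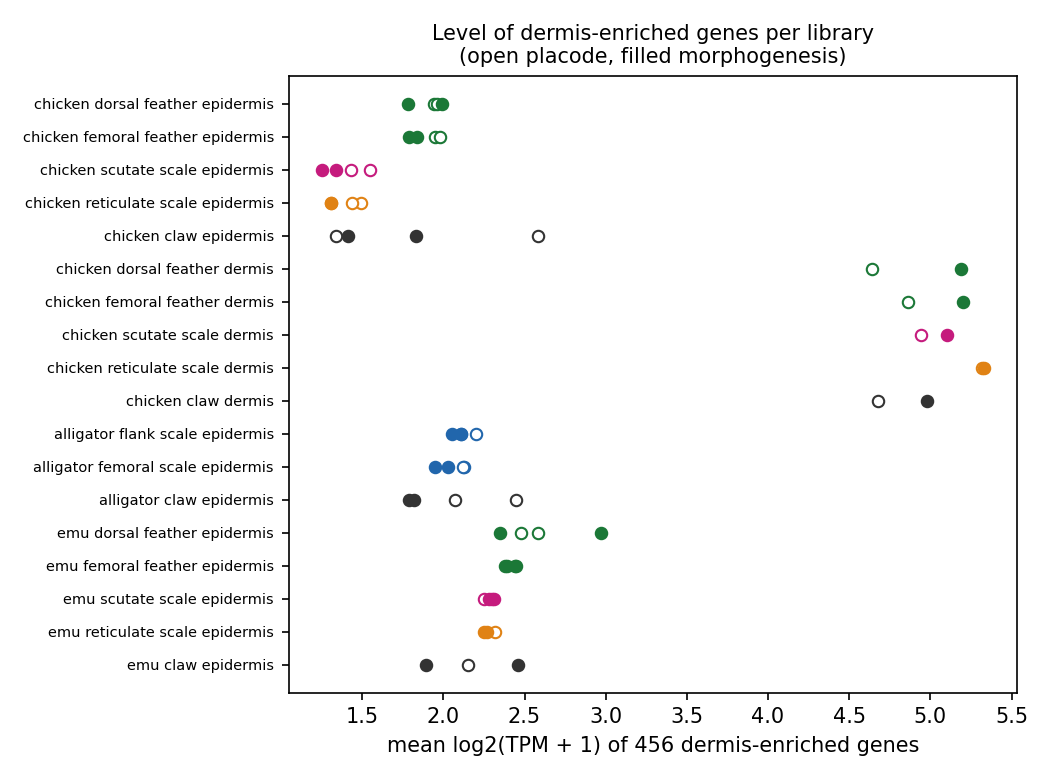
Mean log2(TPM + 1) of 456 dermis-enriched genes in each library (horizontal axis), by species, appendage and layer (vertical axis), with open points for placode and filled points for morphogenesis. Chicken dermis libraries lie between 4.64 and 5.33, and the highest chicken epidermis library, claw placode replicate 2, lies at 2.58.

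Feather dermis and scutate scale dermis of the chicken differed in 130 of 12860 genes, 66 higher in feather and 64 in scutate scale dermis, with both stages serving as repeats and with both feather libraries of a stage from 1 specimen. Most of these were large changes, with 62 and 60 at 2-fold or more. Both placode feather dermis libraries had the lower kind of column total described below, and the other feather and both scutate scale dermis libraries the higher. A term for the kinds was not fitted here, so their part was not tested. Among 12011 genes tested in both, 16 were higher in feather in dermis and in placode epidermis, against 5.8 for independent lists, and 2 were opposite. Of those higher in scutate scale dermis, 5 were so in both layers, against 3.6, and 10 were opposite. Placode dermis and epidermis libraries shared specimens in feather and in scutate scale, which the numbers for independent lists leave out. The log2 differences correlated at 0.04 across genes. The median of all genes lay at 0.112 as deposited and -0.001 after median-of-ratios rescaling, where 51 genes were higher and 66 lower, and the replicate block left 17 genes (8 higher, 9 lower). The count moved with every library left out: 78 without dorsal feather placode, 56 without femoral feather placode, 793 without scutate scale placode, 79 without dorsal feather morphogenesis, 48 without femoral feather morphogenesis and 23 without scutate scale morphogenesis.

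**Figure D4:**
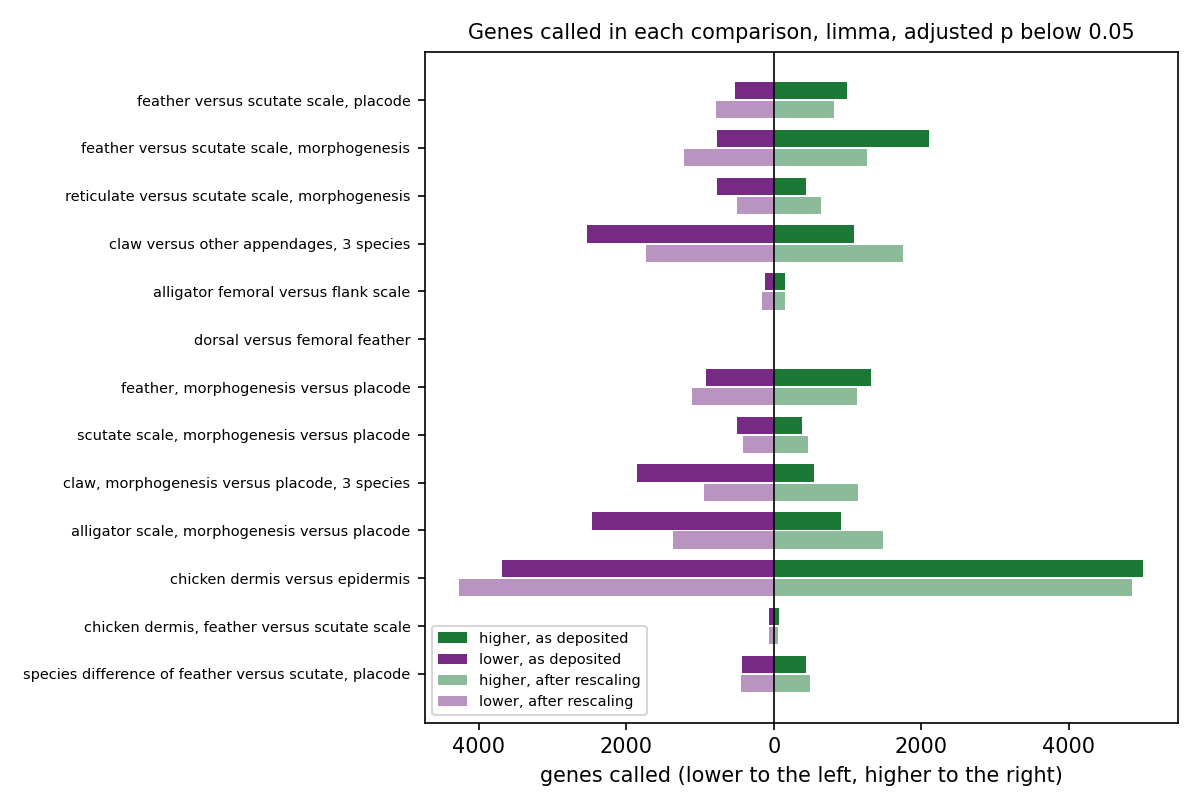
Genes called in each of 13 comparisons at a limma adjusted p below 0.05 (horizontal axis, number of genes, lower to the left and higher to the right of 0), with the TPM values as deposited in dark bars and rescaled by the median of ratios within species in light bars. For feather against scutate scale at morphogenesis the dark bars show 2098 higher and 773 lower genes and the light bars 1267 and 1213.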

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

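The tests of the chicken library kinds and of specimen numbers against column totals, the splits of the alligator site-by-stage difference, the share called among genes at like levels with a library left out, and the splits that keep libraries of a specimen together were chosen only after the result was seen. The contrasts of the claw effect between species, of the feather to scutate difference between stages and of the alligator sites between stages were added after seeing the data.

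Chicken claw placode epidermis carried a replicate that stood apart in dermis-enriched genes. Replicate 2 lay above replicate 1 in 991 of 1101 of these genes, with a mean log2(TPM + 1) of 2.55 against 1.32, and claw placode dermis itself stood at 4.55. Ranked by Spearman correlation with the excess, the claw dermis libraries came 1 and 2 of 10 (0.767 and 0.706, next 0.572). RNA from claw dermis in that library would give such a ranking. Over the 100 most abundant dermis-enriched genes the median excess was 8.9% of the gap from replicate 1 to claw placode dermis (quartiles 5.5 and 16). Of 438 epidermis-enriched genes, 190 were lower in replicate 2, and the median log2 difference of the 438 was 0.08. Dilution by dermis RNA would lower these genes, but an excess of 8.9% would lower them only slightly. That is small beside the log2 differences within this replicate pair (SD 0.856 across 11855 genes), so the median of 0.08 decides nothing. The source of the excess stays open. RNA from another tissue stays open: 0 genes stood at 10 TPM or more here and under 1 TPM in every other chicken library, but all 20 chicken epidermis libraries gave 0, and a tissue whose genes are seen in any other chicken library would not show in that count, although the bound set beforehand was met. The claw comparison gave 3593 genes without the library and 3630 with it, and a real difference between the embryos was not tested.

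Chicken and emu differed in feather minus scutate scale at placode in 865 genes, and among 2441 genes at like levels in chicken dermis and epidermis (within 0.25 log2), 8.4% were called (205 genes, 95% Wilson interval 7.4 to 9.6). That met a bound set beforehand against dermis RNA, but the bound left out the spread between libraries, for the share ran from 3.8% to 10.1% with 1 of the 12 libraries left out and fell under 5% in 2 of these fits, so dermis RNA cannot be told apart here. Nor can it for 447 dermis-enriched genes, where 22.6% were called, 78 higher in chicken and 23 in emu, with a median 0.389 above that of the other genes (camera adjusted p = 5e-05, and adjusted p = 0.92 with an estimated correlation) and feather minus scutate medians of 0.42 in chicken and 0.12 in emu: the species difference did not track the layer difference (Spearman 0.02), but that bound was wrong for a list that holds only genes 4-fold or more apart and was called more often than the genes at like levels. A term for the kinds of chicken library gave 894 genes and decides nothing, because 2 of 4 feather and 1 of 2 scutate libraries were of the low-total kind, so the term could not move the contrast. Of 100 splits of the libraries 3 gave as many genes (highest other 899), but so did 3 of the 21 splits that keep libraries of a specimen together (highest other 1025), so chance cannot be excluded, and a biological difference between the birds stays open, together with their lanes, which were not separated from it.

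The chicken libraries fell into 2 kinds by column total, 16 at 997588 or lower and 14 at 999829 or higher. All libraries of a specimen lay on the same side in 9 of 9 specimens with more than 1 library (permutation test, 100000 resamples, p = 6e-05), which is consistent with a property of the embryo such as its sex. In the low-total samples 10 genes stood at 2 TPM or more in every library and under 1 TPM in every other library, with 0 the reverse, and 39 genes were called higher and 212 lower (median -0.7) of 13645. A lane batch cannot be told apart, because 11 of 30 libraries carry a lane number, the numbers carry no run name, and 1 of 3 lane numbers held both kinds (lane 8, with 5 low-total libraries of 9). No sex label was tested.

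Other differences between groups are given as values. The claw effect differed between alligator and birds in 3376 genes, 2685 with the larger value in alligator, where median-of-ratios rescaling moved the median of all genes from 0.417 to 0.007 and the split to 1444 and 1467 (1477 and 1337 after quantile normalization). It differed between chicken and emu in 3471 genes, 1042 larger in chicken and 2429 in emu, where the median moved from -0.198 to 0.002 and the split to 1608 and 1578 (1487 and 1615). Feather minus scutate scale differed between placode and morphogenesis in 918 genes, 295 larger at placode and 623 at morphogenesis (424 and 452 after median-of-ratios rescaling, 429 and 549 after quantile normalization), with 520 without chicken scutate scale morphogenesis replicate 1 and 579 without emu scutate scale placode replicate 2. Femoral minus flank scale in alligator differed between stages in 818 genes, 345 larger at morphogenesis and 473 at placode (501 and 420 after median-of-ratios rescaling, 568 and 520 after quantile normalization). Without 1 library that count was 134 and 273 without flank scale placode replicates 1 and 2, 544 without femoral scale placode replicate 2, 145 without flank scale morphogenesis replicate 2, and 271 and 285 without femoral scale morphogenesis replicates 1 and 2.

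Single genes differed in size of effect between groups (limma, adjusted p). At placode, feather minus scutate scale was larger in chicken than in emu for ENSGALG00000007466 by 4.52 (SE 1.23, adjusted p = 0.019) and less negative in chicken for ENSGALG00000010923 by 2.05 (SE 0.34, adjusted p = 0.00034). The claw effect in chicken minus emu was -0.93 for ENSGALG00000010923 (SE 0.25, adjusted p = 0.0039), 1.91 for ENSGALG00000001281 (SE 0.43, adjusted p = 0.00081) and 2.4 for ENSGALG00000016584 (SE 0.93, adjusted p = 0.036). In alligator minus birds it was 2.07 for ENSGALG00000001281 (SE 0.35, adjusted p = 5.6e-06), -2.39 for ENSGALG00000014908 (SE 0.34, adjusted p = 4.3e-07) and 2.5 for ENSGALG00000016584 (SE 0.76, adjusted p = 0.0046). Femoral minus flank scale was larger at morphogenesis by 3.11 for ENSGALG00000003323 (SE 0.66, adjusted p = 0.02) and 2.66 for ENSGALG00000016740 (SE 0.28, adjusted p = 0.00094), and differed by -2.5 for ENSGALG00000007219 (SE 0.25, adjusted p = 0.00094).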

How the results depend on the processing

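The term for chicken library kinds, the removal of genes higher in dermis, and the alternatives for alligator scale against claw, the claw effect in alligator minus birds and in chicken minus emu, the changes with stage of feather minus scutate scale and of femoral minus flank scale, and the genes restricted to an appendage were tests chosen only after the result was seen. Over 27 results, 237 of 271 alternatives without left-out libraries left a count within 1.5 times, or a set or correlation with its direction and its side of the threshold or within its spread, and 34 did not. A count within that range does not keep its split: in 28 of 217 alternatives of counts the other side held more genes, 15 of them with another scaling. Fitted alone, species gave other counts, with fewer libraries and another set of genes: feather against scutate placode 1001 in emu, the same at morphogenesis 4684 in chicken and 1444 in emu, reticulate against scutate scale 375 in chicken, claw 9064 in chicken and 5694 in alligator, feather stage 3815 in chicken and 1099 in emu, scutate stage 2407 in chicken and 2 in emu, and dorsal against femoral feather 5 in chicken. Array weights gave 769 for alligator femoral against flank scale, 1601 for its change with stage, 46 for dorsal against femoral feather and 18 for dermis. Quantile normalization gave 455 for femoral against flank scale and 7 for dorsal against femoral feather, which also gave 21 with a pseudocount of 5, 12 with no filter and 5 without trend or robust shrinkage. Dermis feather against scutate scale gave 82 with no filter. Genes restricted to feather numbered 737 after median-of-ratios rescaling and 836 after quantile normalization, and those restricted to claw 1423 and 1173. The correlations with alligator scale minus claw were 0.348 (feather) and 0.329 (scutate) with no filter, over more genes, and 0.429 and 0.422 with a filter at 5 TPM, over fewer. The scutate-higher set gave 0.079 in alligator after quantile normalization, and the feather-higher set, redefined against bird claw, reversed to 0.149 over other genes. Beyond these changes of genes and libraries, the cause was not tested.

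The replicate block moved dorsal against femoral feather to 75 genes and dermis feather against scutate scale to 17. As a fixed term, fitted only to feather libraries of specimens sampled in both tracts, it gave 0 for the tracts by limma (704 at an unadjusted p under 0.05). The fixed term and the loss of libraries cannot be told apart in that count. It moved no other count it was run on by over 1.5 times, although single calls changed: 1369 genes were called in feather against scutate placode, 1368 of them among the 1530. No paired analysis was possible because no specimen number is shared between the compared groups in the alligator fits. Leaving out 1 library changed 32 of 581 fits. The counts then ran from 714 to 1330 for reticulate against scutate scale, from 63 to 256 for alligator femoral against flank scale, from 134 to 661 for its change with stage, from 2 to 12 for dorsal against femoral feather, from 357 to 1218 for scutate stage, from 23 to 793 for dermis feather against scutate scale, from 452 to 895 for the chicken minus emu difference and from 520 to 1181 for the stage difference of feather minus scutate scale. A group left with 1 library was assumed to vary like the others. Without the single emu claw placode library the claw comparison used emu morphogenesis alone, and claw stage gave no value. Over 27 pairings of a named gene with a comparison, in which some genes recur, 811 of 839 settings kept the call, 28 lost it and 0 reversed. TPM keeps no depth, so what depth limits was not assessed.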

Other observations

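The splits of the alligator site-by-stage difference, the splits that part as many specimen pairs in comparisons other than that of the feather tracts, the set shifts divided by the spread of genes, and the correlation with the claw stage effect were tests chosen only after the result was seen. Splits of the libraries into groups of the same sizes bear on whether chance can be excluded, with the real count given beside the highest of the other splits. Since specimen numbers were taken to pair the libraries, splits that part as many pairs of libraries of a specimen as the real one were run too. With the exceptions given below, chance can be excluded where 1 split, the real one, was as large in both kinds. In feather and scutate placodes 1530 genes stood against 658 in 100 splits and 796 in the 21 of the second kind, and at morphogenesis 2871 against 1729 and 1900. For feather stage 2239 stood against 1279 in 100 and 1719 in 30. In 100 of each kind, claw gave 3630 against 2445 and 2469, and chicken layers 8702 against 3 and 1. The claw effect in alligator minus birds gave 3376 against 1937 and 2257, and in chicken minus emu 3471 against 3070 and 3169. Those splits moved claw and reference labels within a species and stage, which takes away the claw effect itself. They cannot test whether the claw effect is alike in the species, so chance is not excluded for these species differences. Genes higher than in each other appendage numbered 1590 against 0 and 707 for feather, 97 against 21 and 26 for scutate scale, 387 against 1 and 62 for reticulate scale, and 616 against 22 and 229 for claw. All splits used the values as deposited and were not run anew after rescaling. After median-of-ratios rescaling the feather count was 737, near the 707 above, so for feather chance is excluded only for the values as deposited. Where no specimen is shared, 1 of 100 splits was as large for claw stage (2398, highest other 2296) and for alligator scale and claw (5694, 4110). Dorsal against femoral feather gave 4 of 100 (3 genes, highest other 9), and of the splits that part as many pairs 1 of 100, the real one (highest other 2). The comparison of the tracts met the bound set beforehand, a share under 0.05, but not the stricter rule used here. By that stricter rule chance cannot be excluded for the feather tracts.

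Beside the feather tracts, the species differences of the claw effect and the chicken minus emu difference of feather minus scutate scale, chance cannot be excluded for 3 results. The stage difference of feather minus scutate scale gave 2 of 100 splits (918 genes, highest other 1114), but 20 of 100 that keep libraries of a specimen together (highest other 2128). The median shift of the bird sets in alligator was as large in 1 of 100 splits, 0.113 against 0.0876 for feather-higher and 0.24 against 0.179 for scutate-higher genes. A shift in log2 grows with the size of all differences, and the real grouping also called the most genes, 5694 against 4110. Divided by the spread of all genes (median absolute deviation), 37 and 26 of 100 splits gave a shift as large (0.176, highest other 0.256, and 0.375, highest other 0.51).

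In 5 comparisons 18 splits exist, too few for a share under 0.05, so chance cannot be excluded there either: reticulate and scutate scale (1209, highest other 1021), scutate stage (875, 744), alligator scale stage (3372, 1458), alligator femoral and flank scale (264, 818) and the change of that difference with stage (818, 264). The split with 818 sets flank placode (stage 22) and femoral morphogenesis (stages 23 to 24) against femoral placode (stage 21) and flank morphogenesis (stage 23). It is also the older against the younger libraries at each stage name, so the alligator scale libraries hold a structure by embryo age, or by site within stage, that the site contrast leaves out, and which of these applies was not tested.

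Embryo age was set against the feather to scutate contrast at placode, since scutate placodes are older. The log2 differences of feather minus scutate scale and of bird claw with stage correlated at r = -0.05 and rho = -0.06 over 6776 genes, from separate libraries.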
